A study of Citrobacter portucalensis with 8 samples.

How the data were processed

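The series measured RNA from *Citrobacter portucalensis* cells recovered from mono-colonized mice (4 libraries) or grown in tryptic soy broth (4 libraries). Per the labels' protocols, total RNA was depleted of ribosomal RNA, fragmented and reverse transcribed with random primers, and dUTP was used in the second strand so that libraries kept strand information. Per the submitters' processing notes, cutadapt 5.0, BWA 0.7.17-r1188, SAMtools 1.21 and featureCounts 2.0.3 were used. The genome build, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. The deposited values were whole-number counts per gene with coordinates, per the file headers, and were not normalized. Coordinates are those of the deposited table, counted from 1.

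All 5045 IDs in the table were of the protein-coding kind and all 5045 lengths were multiples of 3, so lengths are coding lengths. Without names, 53 gene lists fixed before the data were examined, 45 of them with 1068 gene symbols and 8 by product text, could not be matched: 0 symbols were found among the IDs. No gene set test was therefore made, and the alternatives that concern gene set tests or rows of ribosomal and transfer RNA did not apply. No gene function is given for the same reason. IDs are printed by their last part. Of the tested genes, 179 overlapped a gene on the opposite strand, and whether counts of such pairs were told apart depends on the strand setting. Reads shared between near-identical genes were not checked.

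Samples were grouped by the labels. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 3.65 to 17.6 in gut and 4.57 to 40.4 in broth, over genes with at least 20 counts in the pair), so no library was counted as a duplicate. A single count equalled 0.353 to 0.408 CPM in gut libraries and 0.0758 to 0.0959 CPM in broth libraries, and 3 counts equalled 1.06 to 1.22 and 0.227 to 0.288 CPM. Low levels were thus measured less precisely in gut.

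Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 4886 and left out 159, library sizes were scaled with TMM (factors 1.15 to 1.16 in gut and 0.848 to 0.885 in broth), and glmQLFit and glmQLFTest gave two-sided p-values that were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors were derived from the unshrunken fitted log2 fold change and its F statistic, whereas the printed fold changes are the shrunken values of edgeR. CPM values are TMM-scaled, shares of counts are unscaled, and log2 CPM used a prior count of 2. The test of carried-over reads in broth replicate 2 instead added 0.5 CPM, which damps differences of genes near that level. On simulated counts with 4866 genes tested, 62% of 50 genes changed 1.5-fold, 88% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold were recovered, and 9 of 183 calls were false. In the simulation most genes were unchanged, whereas 82.1% of the tested genes were called in the real comparison. These rates therefore do not measure false calls or errors of scaling in the real comparison.

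The rule for named genes took called genes whose libraries did not overlap between groups and whose mean was at least 50 CPM in the higher group, ordered by fold change. Its requirement of a gene symbol or product could not be applied, and it was reduced to 2 genes per direction once the IDs were found to have no names. Runs were at least 6 neighbouring tested genes on 1 strand that were all called in 1 direction with at least 4-fold change, and the 3 longest in each direction were described. The most abundant genes were the 5 with the highest mean share of counts in each group, without correction for length. The test, the rules for runs and abundant genes, the full form of the naming rule, and the alternatives for the counts of called genes at any fold and at 2-fold and for named genes were fixed before the data were examined. The counts of genes at 4-fold and 16-fold, the thinning of broth libraries, and the use of the alternatives on the 4-fold counts and the runs were added after the data were examined.

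The alternatives were median-of-ratios, upper-quartile and total-count scaling, no filter, a filter of at least 10 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, each library left out in turn, and broth libraries thinned to the mean gut total. Reads and unassigned fractions were not analysed here.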

Results

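RNA was sequenced from *Citrobacter portucalensis*, a gram-negative bacterium of the family Enterobacteriaceae, in 2 settings. The gut group held 4 libraries of bacterial cells recovered from the intestine of mono-colonized mice, which are animals that carry this bacterium alone. The broth group held 4 libraries of the same species grown in tryptic soy broth, a rich general-purpose culture medium. The table listed 5045 protein-coding genes on 10 scaffolds. Total counts ranged from 2451950 to 2830029 in the gut libraries and from 10430190 to 13187368 in the broth libraries, a 4.37-fold ratio of the means. Between 39 and 56 genes had a count of 0 in each gut library, and between 32 and 38 in each broth library. The files do not pair the gene IDs with names, so genes and regions are described by position.

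The comparison of both groups asked how the transcriptome of the bacterium in the mouse gut differed from that in laboratory medium. All gut libraries came from cells recovered from animals and all broth libraries from cultures. Differences between the groups therefore cannot be told apart from effects of recovery, handling or growth state. Of 4886 genes tested, 1972 were higher and 2038 were lower in the gut libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 per group). Changes of at least 2-fold were found for 1227 higher and 1245 lower genes, and changes of at least 4-fold for 542 higher and 466 lower genes. This balance depended on the scaling: with total counts only, 1660 genes were higher and 860 lower at 2-fold and 742 higher and 305 lower at 4-fold, and with upper-quartile factors 1483 and 995 at 2-fold and 643 and 358 at 4-fold. At least 16-fold changes were found for 91 higher and 63 lower genes. The 4 gut libraries all lay above the 4 broth libraries for 1854 genes and all below them for 1948 genes, together 77.8% of the tested genes, against 2.86% by chance.

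Libraries of a group resembled each other far more than libraries of different groups. Spearman correlations of log2 CPM across genes, which are not independent replicates, were 0.973 to 0.990 within gut, 0.991 to 0.997 within broth and 0.731 to 0.755 between groups. The first principal component held 92.0% of the variance and separated the groups, and the next held 2.67%. On the latter, gut replicates 1 and 3 lay apart at 19.3 and -20.7, with the other libraries between -1.11 and 1.97. With total counts only, the median log2 fold change moved by 0.403 and the calls became 2520 higher and 1537 lower, 62.1% higher against 49.2% with TMM factors. With upper-quartile factors the median moved by 0.250. All fold changes are relative to the TMM scaling.

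**Figure D1:**
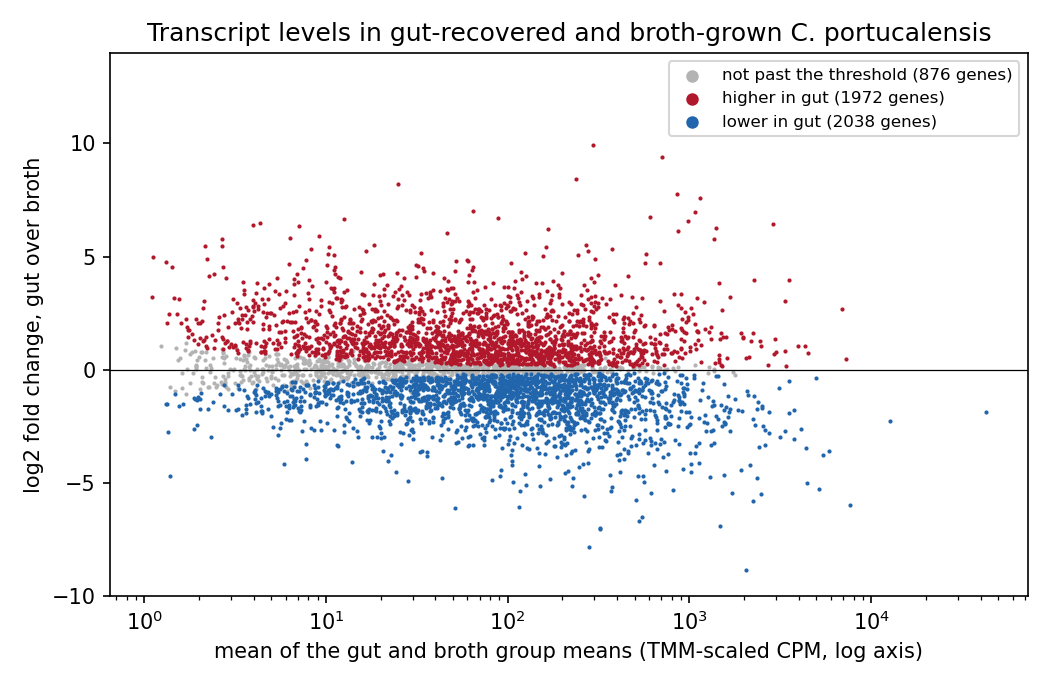
Each point is 1 of the 4886 tested genes, with the mean of both group means in TMM-scaled CPM on a log axis and the log2 fold change of gut over broth on the vertical axis. Red points are the 1972 genes called higher in gut, blue points the 2038 called lower and grey points the 876 genes that did not pass the threshold.

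The largest rise among the genes that met the naming rule was that of peg.2941, which covers bases 565582 to 565899 on the reverse strand of scaffold JH414886.1. Its level was 587 ± 39.7 CPM in gut and 0.569 ± 0.354 CPM in broth (SD, n = 4 each), a log2 fold change of 9.93 with a standard error of 0.193 (edgeR adjusted p = 2.09e-12). Its counts were 1575 to 1908 in the gut libraries and 2 to 9 in the deeper broth libraries. The gene peg.3186, at bases 826313 to 826993 on the reverse strand of the same scaffold, was at 1419 ± 311 CPM in gut and 2.04 ± 0.599 CPM in broth, a log2 fold change of 9.42 with a standard error of 0.226 (edgeR adjusted p = 7.73e-12). The coding region of peg.2941 overlaps 1 other listed gene on its strand, so its count depends on how reads that match both genes were treated.

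The largest fall under the same rule was that of peg.474, at bases 389103 to 389735 on the reverse strand of scaffold JH414878.1. It was at 8.79 ± 2.27 CPM in gut and 4074 ± 1139 CPM in broth (SD, n = 4 each), a log2 fold change of -8.85 with a standard error of 0.252 (edgeR adjusted p = 2.41e-11). Its count was 16 to 31 in the gut libraries and 31546 to 54542 in the broth libraries, where replicate 2 stood apart at 5775 CPM against 3419 to 3663 CPM in the others. The gene peg.3793, at bases 1411823 to 1412152 on the reverse strand of scaffold JH414886.1, was at 2.39 ± 1.48 CPM in gut and 555 ± 137 CPM in broth. Its log2 fold change was -7.83 with a standard error of 0.287 (edgeR adjusted p = 1.70e-10), from counts of 2 to 12 in the gut libraries and 4538 to 7126 in the broth libraries.

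Some of the strong changes lay in blocks of adjacent genes. On 1 strand, 7 runs of at least 6 neighbouring tested genes were all at least 4-fold higher in gut, with 48 of the 542 genes at that threshold, and 6 such runs with 50 of the 466 genes were lower. With total counts only, 9 runs were higher and 4 lower. Of the 4 named genes, 3 (peg.3186, peg.474 and peg.3793) lay in none of these runs. When fold changes were shuffled over the genes 1000 times, the mean number of runs was 0.001 in the higher direction and 0 in the lower, with a highest value of 1 and 0. The shuffle moved genes singly, so it only shows that neighbours did not change independently. Across all close neighbours on 1 strand, log2 fold changes correlated at 0.744 (Spearman), so the shuffle does not set these runs apart from other close neighbours.

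The longest risen run held 10 genes on the reverse strand of scaffold JH414886.1, from base 560604 to 571812, and included peg.2941. Its median log2 fold change was 6.87, with a range of 4.28 to 9.93, and its summed level was 14749 ± 499 CPM in gut and 177 ± 4.19 CPM in broth, an 83.5-fold difference (SD, n = 4 each). Beside it, a run of 8 genes on the forward strand from base 547567 to 557241 fell, with a median log2 fold change of -2.70. The summed level of this fallen run was 2779 ± 249 CPM in gut and 18804 ± 980 CPM in broth, with broth replicate 2 at 20265 CPM and the others at 18184 to 18455 CPM. Only 3362 bases separated these runs. The 3 genes listed between them, from base 557553 to 560521, all rose, with log2 fold changes of 7.03, 5.02 and 6.22.

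**Figure D2:**
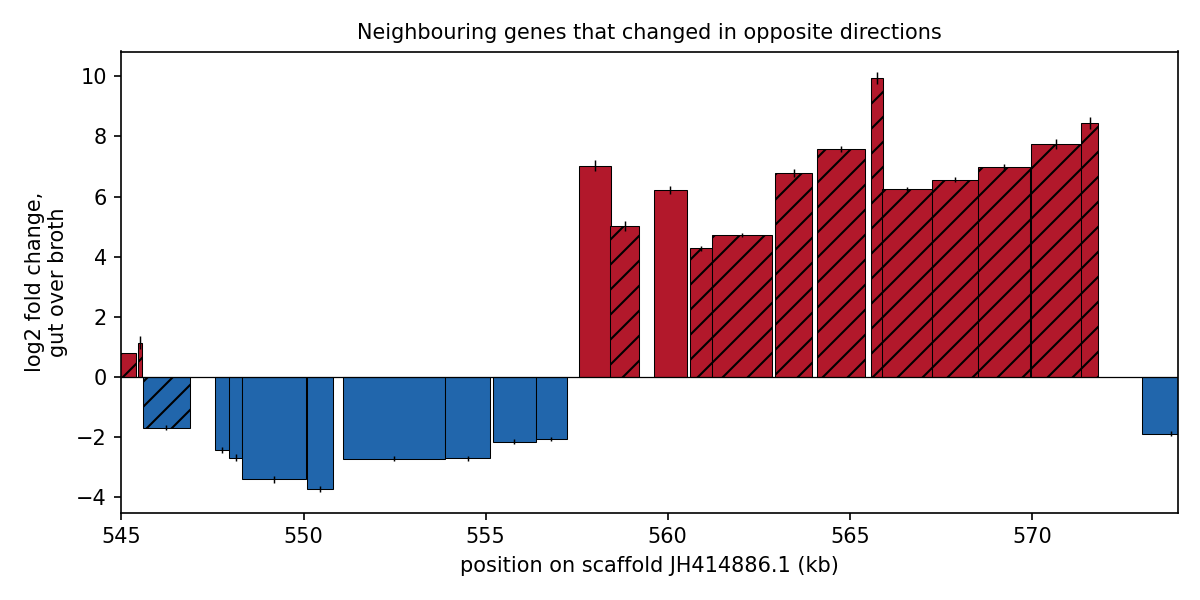
Each bar spans a tested gene on scaffold JH414886.1 (position in kb), its height is the log2 fold change of gut over broth and the thin line is its standard error. Red bars are higher in gut, blue bars lower and hatched bars lie on the reverse strand, and the 8-gene run that fell ends 3362 bases before the 10-gene run that rose.

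A run of 7 genes on the forward strand of scaffold JH414881.1, from base 465694 to 469063, rose with a median log2 fold change of 2.85, from 1212 ± 179 CPM in broth to 8621 ± 1556 CPM in gut (SD, n = 4 each). Another 7-gene run on the forward strand of scaffold JH414886.1, from base 313607 to 322825, rose with a median of 4.38, from 39.2 ± 3.62 to 957 ± 161 CPM, with broth replicate 4 at 33.8 CPM and the other broth libraries at 40.7 to 41.3 CPM. On the forward strand of scaffold JH414878.1, 9 genes from base 282571 to 290449 fell with a median log2 fold change of -6.08, from 7816 ± 225 CPM in broth to 123 ± 6.78 CPM in gut, a 63.7-fold difference. The longest fallen run, 14 genes from base 478664 to 490013 on the same strand of that scaffold, fell with a median of -3.36, from 985 ± 65.3 to 114 ± 16.2 CPM. For each of these 6 runs, all 4 gut libraries lay on 1 side of the 4 broth libraries (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows). The runs were selected on these same libraries, so that p-value only describes them.

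**Figure D3:**
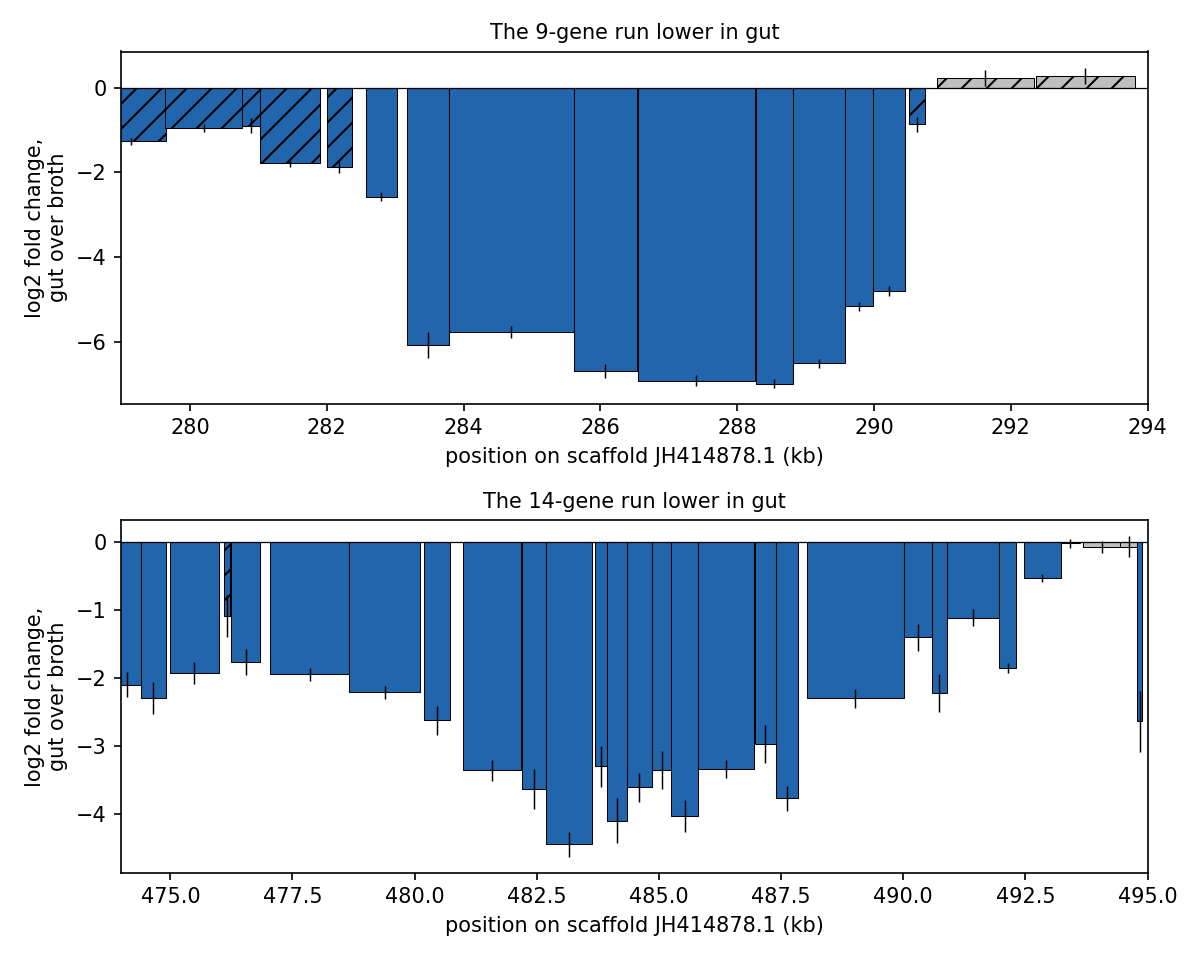
Each bar spans a tested gene on scaffold JH414878.1 (position in kb), its height is the log2 fold change of gut over broth and the thin line is its standard error; hatched bars lie on the reverse strand and grey bars did not pass the threshold. The upper map shows the 9-gene run with a median of -6.08 and the lower map the 14-gene run with a median of -3.36.

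**Figure D4:**
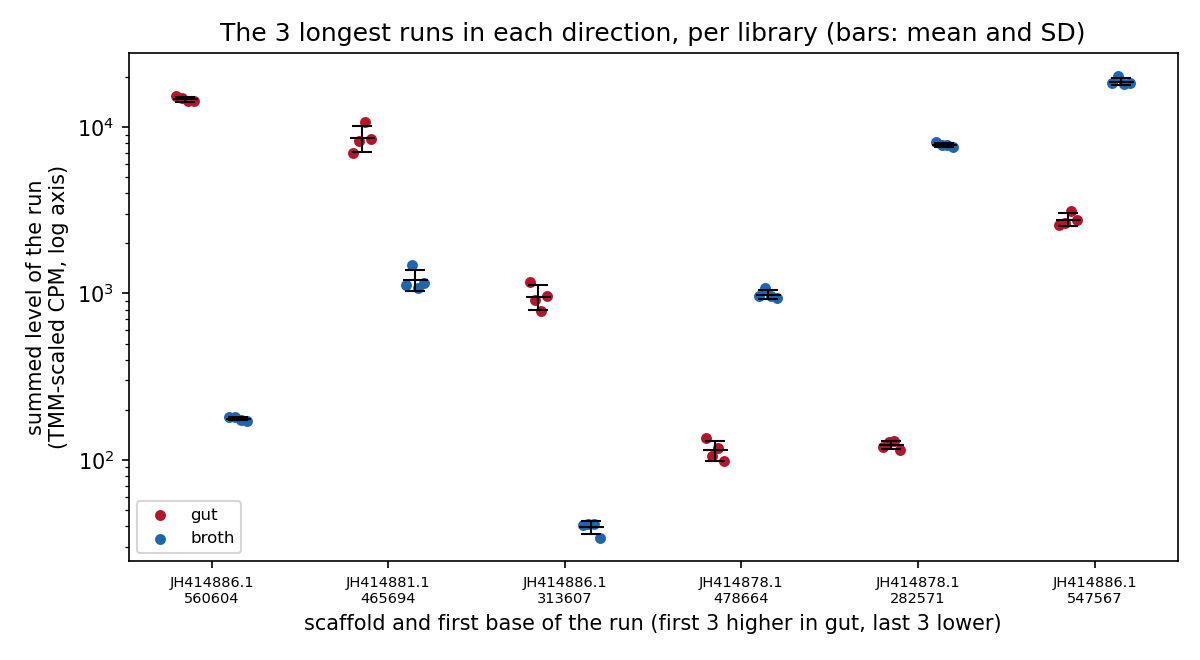
Points are the summed TMM-scaled CPM of each run in each library on a log axis, with the mean and SD of the 4 libraries per group. The 3 longest risen runs stand to the left and the 3 longest fallen runs to the right, and in each run the 4 gut libraries and the 4 broth libraries did not overlap.

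The gene with the largest share of counts was the same in both groups, but its share was smaller in gut. Shares were not corrected for coding length, so they do not rank transcripts by number of molecules. The gene at bases 38795 to 39625 on the reverse strand of scaffold JH414884.1 held 2.12% ± 0.0557 of counts in gut and 5.82% ± 0.207 in broth (SD, n = 4 each), with a log2 fold change of -1.86. The gene at 36926 to 38446 on the same strand rose, with 0.973% ± 0.0550 of counts in gut against 0.527% ± 0.0221 in broth and a log2 fold change of 0.48. The other genes among the 5 with the largest shares in gut were at JH414881.1 from base 228899 (1.38% against 0.161%, log2 fold change 2.69), at JH414882.1 from base 191847 (0.762% against 0.0369%, log2 fold change 3.96) and at JH414885.1 from base 110522 (0.685% against 0.0636%, log2 fold change 3.03).

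In broth, the gene at JH414884.1 from base 601228 held 1.83% of counts against 0.496% in gut, with a log2 fold change of -2.29. The gene at JH414886.1 from base 2621676 held 1.31% against 0.0274%, with a log2 fold change of -5.98. Genes at JH414878.1 from base 547523 and at JH414886.1 from base 1193612 held 0.944% and 0.875% of broth counts and 0.103% and 0.0840% of gut counts, with log2 fold changes of -3.60 and -3.78. The share of the gene from base 1193612 was 0.545% in broth replicate 4 and 0.977% to 0.997% in the other broth libraries. The 10 genes with the most counts in each library together held 9.06% ± 0.267 of counts in gut and 14.3% ± 0.355 in broth.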

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

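The tests of sequencing depth and of a few genes for broth replicate 2 were set or revised after results were seen. The test of carried-over reads was set before its result was seen, but after broth replicate 2 was seen to lie apart. Among 60 sets of 4 libraries examined, 5 held a library far from the other 3, where about 3 would be so by chance (1 in 20).

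In broth replicate 2, peg.474 was at 5775 CPM against 3419 to 3663 CPM in the other broth libraries. The gene at JH414881.1 from base 228899 held 0.188% of counts in broth replicate 2 against 0.150% to 0.156% in the others. The 8-gene run at JH414886.1 from base 547567 summed to 20265 CPM in broth replicate 2 against 18184 to 18455 CPM. In broth replicate 4, the gene at JH414886.1 from base 1193612 held 0.545% of counts against 0.977% to 0.997%. In the same library the 7-gene run at JH414886.1 from base 313607 summed to 33.8 CPM against 40.7 to 41.3 CPM. Among all libraries, gut replicates 1 and 3 had the most genes over 1.5-fold off the mean of the others of their group, 589 and 641, against 396 and 347 in the other gut libraries, 263 in broth replicate 2 and 160 to 176 in the other broth libraries. Without gut replicate 1 the calls were 1992 higher and 2038 lower, and without gut replicate 3 they were 1982 and 2037.

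Within the broth group, replicate 2 held 3 of these 5 values, and without it the biological coefficient of variation of broth fell from 11.9% to 6.09%. Sequencing depth was argued against, as the total of replicate 2, 11137231 counts, lay within the range of the other broth libraries, 10430190 to 13187368. Thinning to the lowest total could thus change little. After it, in 20 draws, the highest Spearman correlation of replicate 2 with another broth library averaged 0.991, below the lowest value among the other 3, 0.997. Reads carried over from gut libraries were argued against as well, since the 91 genes at least 16-fold higher in gut differed from the other broth libraries by a median log2 of 0.055 (95% bootstrap interval -0.058 to 0.10). A few deviating genes did not account for it, because with each library's own 5% of genes farthest off left out its mean squared deviation was still 1.78 times that of the others (1.66 to 1.91, against 2.08 with all genes). A difference in culture or handling stays open, and no biological explanation was tested because the labels describe the broth libraries alike.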

How the results depend on the processing

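The thinning of the broth libraries, and every alternative for the 4-fold counts and the runs, were chosen after the data were seen. Of the counts of genes and runs under all alternatives, 135 stayed within 1.5 times the value reported. The exception was the count of genes at least 4-fold lower, 466, which was 305 with total counts only. That scaling moved fold changes nearly alike, by a median log2 of 0.403 (SD over genes 0.0024), and the shift alone gave 305. Under it, 475 calls were lost, 164 called genes turned sign, and 26 of these, with log2 fold changes of -0.27 to -0.15 before, were called in the opposite direction, each of which the shift alone turns. The 4 named genes kept their direction and side of the threshold in 17 alternatives each: log2 fold changes were 9.69 to 10.33 for peg.2941, 9.10 to 9.82 for peg.3186, -8.95 to -8.44 for peg.474 and -8.18 to -7.42 for peg.3793, with a largest edgeR, DESeq2 or limma adjusted p of 3.67e-07. The median of each described run kept its sign, with 86 values within the replicate spread and 16 beyond it. Leaving out each library in turn gave 1901 to 1992 higher and 1954 to 2038 lower genes. DESeq2 gave 2032 and 1996, with 12 adjusted p-values missing, and limma-voom 1976 and 2042. With broth thinned to gut depth, 4695 genes were tested, and 1938 were higher and 1873 lower, of which 3742 had the call and direction reported. Depth limits genes near 3 counts per library. The replicate block gave 1946 higher and 2017 lower genes. Deviations of same-numbered gut and broth libraries correlated at -0.034, 0.020, 0.016 and 0.0021, and 1 of 4 gut libraries correlated best with its own number. No pairing by number was thus seen in these values, which cannot show that the design held none. Gene set tests and the removal of ribosomal and transfer RNA rows were not run.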

Other observations

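The 2-fold runs, the neighbour correlations, the length classes and the counts per scaffold were examined after the data were seen, and each test of short genes and of scaffold JH414878.1 was set or revised after results were seen; the counts over other splits were set before any of those splits was fitted, although the 4-fold counts they include had been added after the data were seen.

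At a 2-fold threshold, 12 runs were higher and 14 were lower in gut. The longest held 28 genes on the forward strand of JH414881.1 from base 465694 to 479343, and rose from 11698 ± 678 to 39455 ± 3060 CPM in sum (SD, n = 4 each), with a median log2 fold change of 1.69. Fallen runs of 20 genes lay on the forward strands of JH414878.1 from base 476241 to 492313, with a median of -3.14, and of JH414886.1 from base 2008920 to 2023052, with a median of -1.72.

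Neighbouring genes changed together most where they lay close on 1 strand. Across 1820 pairs of tested genes under 50 bases apart, the Spearman correlation of log2 fold changes was 0.744, against 0.416 at 50 to under 200 bases and 0.173 at 200 bases or more. Divergent neighbours correlated at 0.255 and convergent neighbours at 0.185. The highest absolute values in 1000 shuffles were 0.0758, 0.143, 0.168, 0.126 and 0.122 in the same order. Genes are not independent replicates, and pairs share genes.

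The 35 splits of the 8 libraries into 4 and 4 were each fitted with edgeR. For the counts of higher and lower genes at an adjusted p under 0.05 (1972 and 2038), at 2-fold (1227 and 1245), at 4-fold (542 and 466) and for the runs (7 and 6), only 1 of the 35 splits, the real one, gave as many, and the highest of the others was 0. At an unadjusted p under 0.05, the highest of the other splits gave 184 genes and the real split 4057; no other tool was run on the splits. A chance assignment of these 8 libraries to the groups is argued against, with 1 of 35 the smallest share these splits can give. Chance differences between the sources of the libraries stay open, because the labels do not say whether replicates came from separate mice or cultures. The other splits hold the gut and broth difference within their groups, which raises their spread, so their counts of 0 do not measure how many calls are false.

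Genes of up to 200 bases were more often higher in gut: 127 of 243 tested were higher and 63 lower, with a median log2 fold change of 0.77 against -0.04 in longer genes. A gradual length bias is argued against, because genes over 200 and up to 300 bases lay below genes over 1000 bases of matched level (median log2 difference -0.41, 95% bootstrap interval -0.75 to -0.10). That comparison does not cover a bias confined to genes of up to 200 bases, which was not tested. Unequal counting noise from the shallower gut libraries was examined by thinning broth to gut depth. With no filter after thinning, the same 243 genes had a median of 0.87 (0.45 to 1.07). The 183 that pass the filter after thinning had 0.69 against 0.65 before it. The median thus did not fall when the broth libraries had gut depth. Thinning left the gut counts and, for the 243, the choice of genes as they were. A bias from noise in the gut counts could therefore not be revealed and stays open. Low counts cannot be told apart from an effect of length: against longer genes matched on mean log2 CPM the difference shrank to 0.29 (0.03 to 0.72), which spans the bound of 0.2, and the short genes in the highest of 4 abundance classes had a median of -0.16. A permutation test that rotated level-adjusted log2 fold changes along the genome gave p = 0.0088 for short against longer genes. That test asks for a difference of any size and does not use the bound. A response of short genes to the gut or a bias confined to their length may remain, but part of the difference goes with their low level. The 31 short genes that overlap another listed gene had a median of -0.03 (-0.54 to 1.59) against 0.89 (0.61 to 1.14) in the other 212.

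On scaffold JH414878.1, 165 genes were higher and 264 lower in gut, 38.5% higher among those called. The departure did not pass a permutation test that rotated calls along the genome to keep neighbours together (permutation p = 0.0166, adjusted p = 0.166 over 10 scaffolds). A few long runs cannot be told apart from a scaffold-wide shift, since with tested neighbours under 50 bases apart on 1 strand counted once, by the median of their called genes, 40.8% of 262 such groups were higher (95% exact binomial interval 34.8% to 47.1%, bound 46%), against 51.7% of 2433 on the other scaffolds. Fewer copies of the scaffold in gut cannot be told apart either: the highest median log2 fold change among 4 consecutive parts with nearly equal gene numbers was 0.057 (bootstrap interval -0.39 to 0.29, bound -0.2). The lean was largest in the last part, from base 434833 to 553411, with 29 higher and 83 lower genes (median -1.18). In order along the scaffold, the earlier parts had 60, 39 and 37 higher genes and 55, 61 and 65 lower genes. Their medians were 0.057, -0.26 and -0.37, so the lean was not confined to the last part.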
